A study of Mus musculus with 30 samples.

How the data were processed

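The libraries came from B cells of B16F10-bearing wild-type C57Bl6J mice. Per the labels' protocols, 1000 live cells were double-sorted per library, either all B cells with a gate written as CD45+ CD3e- CD138+ CD19+/- or B cells with and without surface TIM-1, and lysed at once, and cDNA was made by a modified SMART-Seq2 method that copies full-length polyA RNA. The gate names no myeloid marker. The authors' deposited table held TPM, a length-corrected share of all transcripts, for 23420 genes, of which 21459 were above 0 in at least 1 library, in 1 column for each of the 30 libraries. All columns were matched to samples by name, with 0 left over. The submitters' processing notes name the genome build mm10 and the tools bcl2fastq, RSEM 1.2.8, GenomeStudio and DESeq2 1.28.1, with no role or order. The aligner, the annotation and any filter are not given in the sources used here. TPM keeps no read totals, so the depth per library is unknown, no count model was fitted and no value carries a counting interval. Of 18 housekeeping genes, 0 were listed at 0 in any library.

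Groups were taken from the tissue and cell type in the labels, giving 10 groups of 3. Values were tested as log2(TPM + 1), keeping genes with at least 1 TPM in at least 3 libraries of the fit. Fold changes on this scale understate the change of genes with low values. The 18 TIM-1 positive and negative libraries made a fit of 6 groups with 12539 genes, and the 12 libraries of all B cells a fit of 4 groups with 12213 genes. Each comparison was a contrast in limma 3.58.1 (lmFit, contrasts.fit and eBayes with an intensity trend, in R 4.3.3), two-sided, with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Errors of log2 differences are limma's moderated standard errors, and errors of TPM are SDs of 3 libraries. The contrasts were TIM-1 positive minus negative as the mean of 3 tissues and in each tissue, 2 differences of that difference between tissues, tumor minus the mean of the 3 lymphoid tissues, draining minus non-draining nodes, and spleen minus the mean of both kinds of node.

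Gene lists of B cell states, functions and other cell types that the gate could hold, 32 in all, were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists within a comparison. A list needed 3 genes in the fit, which left 30 lists in the sorted fit and 28 in the fit of all B cells. Of the 12 constant region genes of immunoglobulins, 0 were in the table, so that list was not tested. The lists, the contrasts, the tests, the alternatives other than those said to be added, and the rule for naming genes were set before the data were examined. For the TIM-1 mean, the tumor, the spleen and the node comparisons, the rule named up to 12 genes in each direction with the largest log2 difference among genes past the test, with at least 10 TPM on the higher side and the same direction in every tissue contrast. Predicted genes, variable segments of antigen receptors, mitochondrial and sex-linked marker genes were left out. For contrasts within a tissue or between tissues it named up to 5 each way, and for each list up to 4 members with the smallest adjusted p, or 2 with the highest TPM where none passed. Havcr1 was named in every group. Other genes are said to be chosen after their values were seen. Gene positions came from GENCODE vM21 on GRCm38, the same build as mm10, matched by symbol.

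Alternatives were a pseudocount of 0.1 or 5, no filter or a filter of 5 TPM, quantile normalization, median-of-ratios scaling, array quality weights, no intensity trend, a robust variance fit, other sets of libraries in the fit, a 2-fold minimum, the replicate number as a block over all tissues or within each tissue, and each library left out in turn. For lists they were an estimated correlation, fry and lists without shared genes. Added after seeing the data were fits without the 2 libraries that stood apart, scaling of each library to the 12 B cell identity genes, and TPM recomputed without Rn45s, Gm20594 and the hemoglobin genes. Median-of-ratios scaling was planned for genes, but for lists it too was added. Whether replicate numbers pair the libraries was checked by correlating deviations from the group means over genes. Of 45 pairs of groups, 2 had every same-numbered r above 0.1, both in spleen: all against TIM-1 negative cells (0.114, 0.113 and 0.274) and TIM-1 negative against positive cells (0.105, 0.106 and 0.224). The labels give no source for that pairing.

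Each count of called genes was also computed for other splits of the same libraries, all 10 for 6 libraries and otherwise 100 drawn with a fixed seed. The steps were tested on simulated data with 100 changed genes per size. For the TIM-1 mean, 48% of genes with a log2 change of 1 and 76% of those with a change of 2 were recovered, and for the tumor comparison 39% and 81%. In draining nodes alone, TIM-1 changes of these sizes were recovered for 3% and 30%, and differences of the TIM-1 difference between nodes for 0% and 9%. Transcripts were searched for shared stretches with blastn 2.17.0. Other steps used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.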

Results

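B cells were sorted from C57Bl6J mice bearing B16F10 melanoma, a pigmented mouse skin tumor line, and their polyA RNA was sequenced as full-length cDNA from 1000 cells per library. The table held 23420 genes in 30 libraries. They formed 10 groups of 3: all B cells from the tumor, and all B cells, TIM-1 positive B cells and TIM-1 negative B cells from tumor-draining lymph nodes, non-draining lymph nodes and spleen. Between 8237 and 11693 genes per library reached 1 TPM. TPM values keep no read totals, so the depth of each library is unknown and no counting interval can be given. Of the 30 libraries, 2 stood apart. Replicate 1 of the TIM-1 negative cells of draining nodes had 10059 genes above 0, against 12688 to 14516 in the others, a mean of 238 TPM over the B cell identity genes and 419 TPM over the T cell genes. In replicate 3 of the TIM-1 positive cells of spleen, hemoglobin transcripts made up 17.9% of all TPM. The series names 3 mice but does not tie each library to a mouse, so the p-values measure the spread between these libraries. No pair of libraries held identical values.

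Havcr1, which encodes TIM-1, the surface protein used for the sort, averaged higher in TIM-1 positive than in TIM-1 negative libraries of every tissue. The gene lies on chromosome 11 from 46735080 to 46779578 in GRCm38. In draining nodes it reached 46.4 ± 48.2 TPM (SD, n = 3) in TIM-1 positive cells, while the 3 TIM-1 negative libraries list it at 0. In non-draining nodes it measured 29.0 ± 32.9 TPM in positive and 2.48 ± 3.21 TPM in negative cells. In spleen it measured 26.1 ± 14.2 TPM in positive and 3.96 ± 5.46 TPM in negative cells. Among all B cells it stood at 5.45 ± 4.64 TPM in draining nodes, 3.97 ± 1.51 TPM in non-draining nodes, 4.15 ± 4.42 TPM in spleen and 0.51 ± 0.537 TPM in the tumor. The TIM-1 positive libraries exceeded the negative ones by 3.63 ± 0.54 on the log2(TPM + 1) scale over the 3 tissues (limma, adjusted p = 0.00165). By tissue the difference was 5.08 ± 0.94 in draining nodes (adjusted p = 0.0114), a size that rests on the pseudocount because one side is listed at 0 and that did not pass without TIM-1 positive replicate 1 (adjusted p = 0.0798), 2.93 ± 0.94 in non-draining nodes (adjusted p = 0.342) and 2.87 ± 0.94 in spleen (adjusted p = 0.532). Because TIM-1 chose the cells, this difference checks the labels and is not a finding. In the tumor, Havcr1 was lower than in the lymphoid tissues, with a log2 difference of -1.67 ± 0.54 (adjusted p = 0.029). That call was lost without tumor replicate 2 (adjusted p = 0.118), without tumor replicate 3 (0.0751), with a pseudocount of 5 (0.0616), with no filter (0.0701), with array weights (0.187), with all 30 libraries in the fit (0.112) and with scaling to the B cell identity genes (0.0856).

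**Figure D1:**
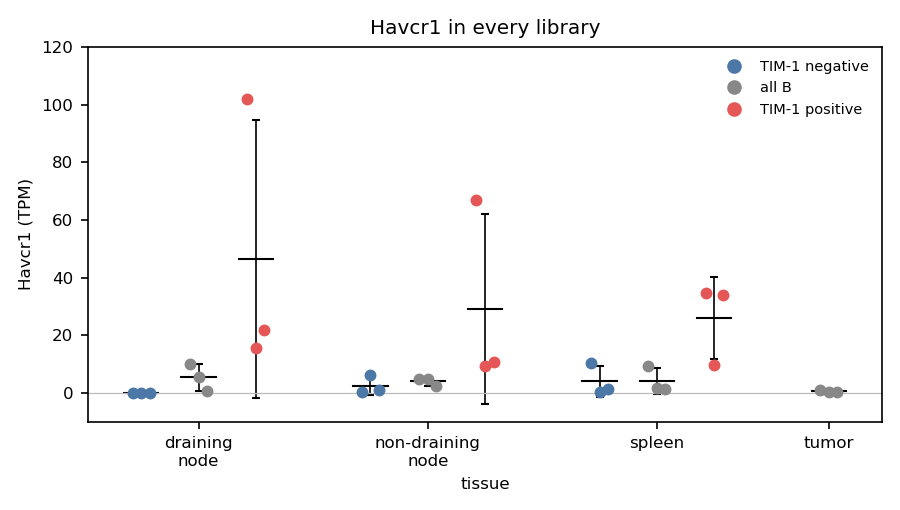
Havcr1 in TPM for each library (points) by tissue and sorted fraction, with the mean and SD of each group of 3. TIM-1 positive libraries of draining nodes averaged 46.4 TPM and the tumor libraries 0.51 TPM.

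The first comparison asked how B cells carrying the TIM-1 checkpoint molecule differ from those without it. TIM-1 positive libraries held more of the transcripts of dividing cells and of phagocytes. Igj, the joining chain of secreted antibodies, averaged 635 TPM in TIM-1 positive and 79.8 TPM in TIM-1 negative libraries, a log2 difference of 4.95 ± 0.95 (limma, adjusted p = 0.013, n = 9 against 9). Ccnb2, a mitotic cyclin, rose from 9.27 to 57.3 TPM, by 3.42 ± 0.46 (adjusted p = 5.48e-04), and Ccna2 and Cdkn3, 2 further cell cycle genes, rose by 3.02 ± 0.59 and 3.00 ± 0.38. Fcer1g, the shared signaling chain of Fc receptors, rose from 15.4 to 162 TPM, by 3.25 ± 0.54 (adjusted p = 0.0052). Trf, which encodes transferrin, rose from 5.04 to 48.2 TPM, by 3.37 ± 0.43 (adjusted p = 3.27e-04). Genes of phagocytes rose as well: the heme oxygenase Hmox1 by 3.11 ± 0.71, the lectins Cd209b by 2.99 ± 0.68 and Clec4n by 2.96 ± 0.46, the lysozyme Lyz1 by 2.96 ± 0.52, and S100a4 by 3.06 ± 0.65. Gpr183, the oxysterol receptor that guides B cells inside follicles, fell from 115 to 59.5 TPM, by 1.03 on the log2 scale (SE 0.21, adjusted p = 0.0184). Treml2, a surface receptor of B cells, fell from 56.4 to 26.3 TPM, by 1.14 (SE 0.16, adjusted p = 0.00104). Tnfrsf12a, Rrad, Fam214b and Tcp11l2 had log2 differences of -2.24 ± 0.49, -1.75 ± 0.40, -1.65 ± 0.35 and -1.10 ± 0.20. In all, 180 of 12539 genes passed, 124 higher and 56 lower in TIM-1 positive cells, and 1844 had an unadjusted p under 0.05. The median difference over all genes tested was -0.09, and with scaling to the B cell identity genes 0.15. The split of higher against lower calls was 152 to 26 with median-of-ratios scaling and 115 to 1 with B cell identity scaling. With TPM recomputed without Rn45s, Gm20594 and the hemoglobin genes it was 147 to 36, and the median over all genes was -0.011. The count was 327 (145 higher, 182 lower) without replicate 1 of TIM-1 negative draining nodes and 322 without both libraries that stood apart. It was 117 without draining replicate 2, 104 and 97 without non-draining replicates 1 and 3, and 100, 107 and 116 without spleen replicates 1, 2 and 3, all of them TIM-1 negative. The calls of Hmox1, Cd209b, S100a4, Gpr183, Tnfrsf12a, Rrad and Fam214b were each lost with at least 1 library left out, and those of Gpr183, Treml2, Tcp11l2, Rrad and Fam214b with B cell identity scaling. The call of Igj was lost with TIM-1 positive and negative libraries of the same number as a block within each tissue (adjusted p = 0.0759).

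A few transcripts were higher in every TIM-1 positive library than in any TIM-1 negative library of the same tissue. They were singled out after their values were seen. Gm20594, a predicted gene on chromosome 6 from 79817916 to 79818364 in GRCm38, had the smallest p. It rose from 13120 ± 844 to 44400 ± 11360 TPM in draining nodes, from 13450 ± 306 to 74070 ± 7938 TPM in non-draining nodes and from 13970 ± 789 to 62730 ± 13080 TPM in spleen (SD, n = 3). The log2 difference was 2.11 ± 0.10 (adjusted p = 1.06e-09). Its transcript of 449 bases matched the mitochondrial 16S ribosomal RNA gene mt-Rnr2 at 88.5% identity over 435 bases, and the table held 0 mitochondrial genes, so its value is uncertain. The call was lost with quantile normalization (0.77, adjusted p = 0.188) and held with median-of-ratios scaling (2.23, adjusted p = 4.06e-08). Quantile normalization gives genes of the same rank the same value in every library. It thus limits by construction the change of a gene this abundant, so that loss decides little. Grk4, a receptor kinase gene, rose by 1.73 ± 0.14 (adjusted p = 2.91e-06) and Kcnq1ot1, an imprinted antisense RNA, by 1.5 ± 0.14 (adjusted p = 1.5e-05). Their transcripts share a stretch with 373 and 749 other genes, so these 2 values are uncertain as well. In total 47 called genes were higher and 18 lower in this complete way in all 3 tissues. Of all 12539 genes tested, 64 were higher in this way, against 1.57 expected by chance.

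Among the gene lists, 6 were higher and 2 lower in TIM-1 positive cells, and 22 of 30 did not pass. Cell cycle genes rose together, with a median log2 difference of 1.43 over 20 genes (camera, adjusted p = 2.53e-18, but adjusted p = 0.0961 with an estimated correlation). Of these, 5 were called over all genes and 17 adjusted over the list alone, among them the proliferation marker Mki67 (2.58 ± 0.45, adjusted p = 0.00689) and the topoisomerase Top2a (2.19 ± 0.44, adjusted p = 0.0178). Germinal center genes rose by a median of 1.5 over 12 genes (adjusted p = 2.04e-07, but adjusted p = 0.206 with an estimated correlation). Over all genes 3 were called, and adjusted over the list alone 10 were higher and 2 lower. In spleen alone the list was at 0.26 with 5 of 12 genes negative (adjusted p = 0.197). The called genes included Nuggc (2.60 ± 0.57) and Gcsam (2.49), genes of the germinal center B cell program. The calls of Nuggc, Gcsam and Spn were each lost with at least 1 library left out. B-1 and innate-like genes rose by a median of 0.89 over 10 genes (adjusted p = 2.77e-04, and 0.0221 with an estimated correlation). Only Spn, which encodes CD43, was called (0.93 ± 0.22, adjusted p = 0.0491), and 3 passed adjusted over the list alone. Plasma cell genes rose by a median of 0.44 over 15 genes (adjusted p = 0.00129, but adjusted p = 0.312 with an estimated correlation), with 1 called, Igj, and 3 adjusted over the list alone. In non-draining nodes alone the plasma cell list was at -0.12 with 9 of 15 genes negative (adjusted p = 0.848). Naive follicular genes were lower by a median of -0.50 over 12 genes, 11 of them negative (adjusted p = 1.08e-04, but adjusted p = 0.385 with an estimated correlation). By limma 0 of them were called, 7 had an unadjusted p under 0.05 and 7 passed adjusted over the list alone. The low-affinity IgE receptor Fcer2a differed by -0.45 ± 0.31 and the homing receptor Sell by -0.68 ± 0.18, and neither passed. MHC class II genes were lower by a median of -0.31, with all 10 negative (adjusted p = 0.0445, but adjusted p = 0.736 with an estimated correlation). By limma 0 of these were called, 0 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone. H2-Ab1 differed by -0.35 (adjusted p = 0.455) and H2-Aa by -0.25 (adjusted p = 0.652). The MHC class II call was lost with quantile normalization (adjusted p = 0.106), median of ratios (0.0503), B cell identity scaling (0.161) and the replicate block (0.0604).

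Transcripts of other cell types moved with TIM-1. Macrophage and monocyte genes rose by a median of 1.59 over 11 genes (adjusted p = 1.44e-14, and 0.0221 with an estimated correlation). Of these, 6 were called over all genes and 9 adjusted over the list alone, including Lyz2 (2.94 ± 0.42, adjusted p = 0.00108), the growth factor receptor Csf1r (2.80 ± 0.52, adjusted p = 0.0101), the complement gene C1qa (2.47 ± 0.45, adjusted p = 0.0101) and Cd68 (2.13 ± 0.35, adjusted p = 0.00399). The mean of the macrophage genes was 146 ± 85.3 TPM in TIM-1 positive and 22.2 ± 12.1 TPM in TIM-1 negative cells of draining nodes, 102 ± 61.8 against 30.8 ± 8.05 TPM in non-draining nodes and 95.7 ± 34.8 against 45.0 ± 13.8 TPM in spleen. Dendritic cell genes rose by a median of 1.21 over 10 genes (adjusted p = 1.56e-07, and 0.0225 with an estimated correlation), with 1 called, Clec9a (1.46 ± 0.27, adjusted p = 0.0101), and 4 adjusted over the list alone. That mean too rests on draining nodes, since the dendritic cell list was at 0.13 in non-draining nodes (adjusted p = 0.642) and 0.27 in spleen (adjusted p = 0.0552). The B cell identity genes had a median difference of -0.25 (adjusted p = 0.133) and the T cell genes of -0.38 (adjusted p = 0.226), and neither list passed. Without replicate 1 of TIM-1 negative draining nodes, the B cell identity genes fell, with a median of -0.54 and 6 of 12 called (adjusted p = 2.76e-08, but p = 0.0535, not adjusted, with an estimated correlation). Of the co-inhibitory receptors, the checkpoint molecules of the series title, Havcr2, which encodes TIM-3, rose by 1.11 ± 0.21 (adjusted p = 0.0135). This mean rests on draining nodes, where Havcr2 rose by 3.27 ± 0.37 (adjusted p = 2.37e-04), against 0.004 in non-draining nodes (adjusted p = 1) and 0.05 in spleen (0.996). The dendritic cell list had the same tissue pattern, so dendritic cells in the sort cannot be told apart from B cells as the source of Havcr2. Lag3 differed by 1.41 ± 0.42 (adjusted p = 0.124), Tigit by 0.50 ± 0.58 (0.722), Pdcd1 by 0.11 ± 0.72 (0.956) and Cd274 by -0.66 ± 0.25 (0.235), and the last 4 genes were chosen after the values were seen. Lag3 passed with a pseudocount of 5 (limma, adjusted p = 0.0458) and with all 30 libraries in the fit (0.0477).

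**Figure D2:**
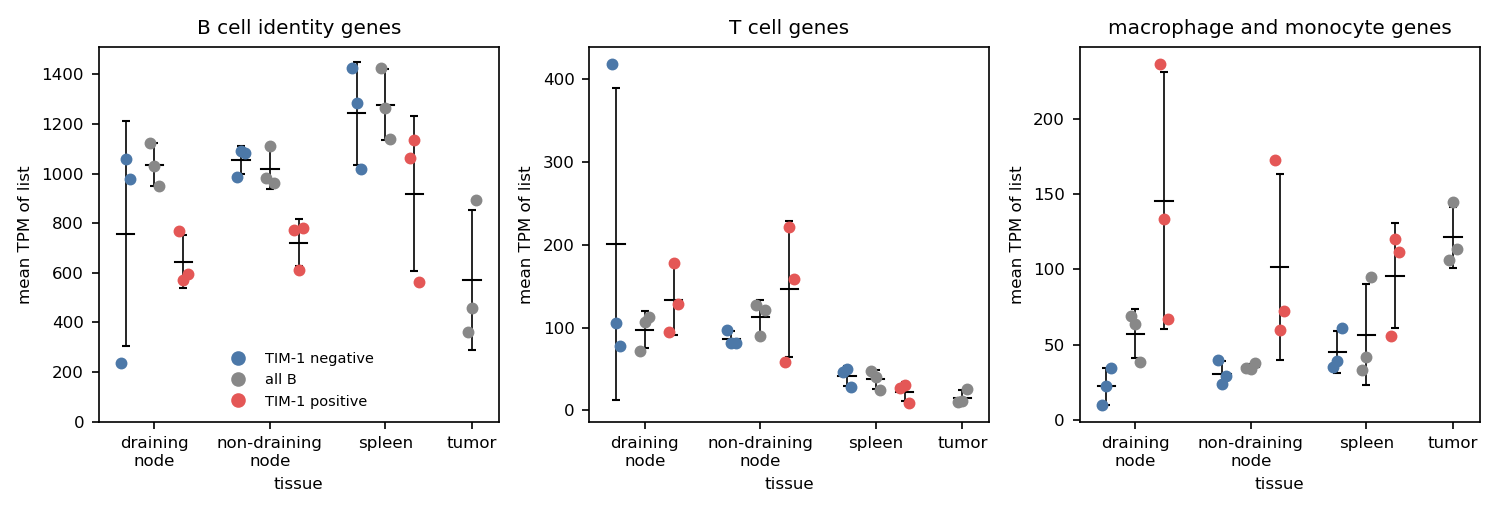
Mean TPM per library (points) of the B cell identity, T cell and macrophage gene lists by group, with the mean and SD of 3 libraries. The macrophage genes averaged 146 TPM in TIM-1 positive and 22.2 TPM in TIM-1 negative cells of draining nodes.

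**Figure D3:**
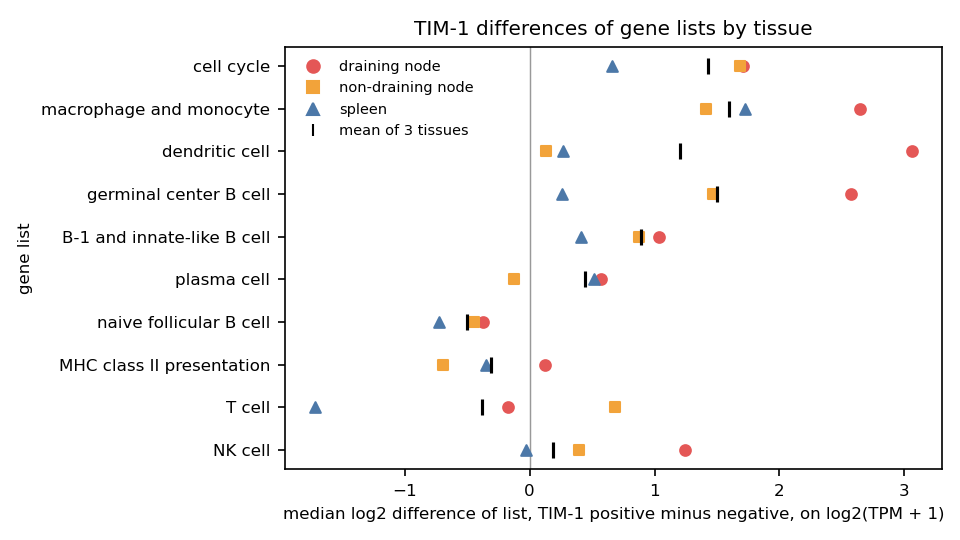
Median log2 difference between TIM-1 positive and TIM-1 negative libraries for 10 gene lists in draining nodes, non-draining nodes and spleen, with a mark for the mean of the 3 tissues. The cell cycle list had a median of 1.43 and the macrophage list of 1.59 for that mean.

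Within draining nodes, TIM-1 positive libraries held far more myeloid transcripts than TIM-1 negative ones. Ccl8, a monocyte-attracting chemokine, averaged 454 against 4.2 TPM, a log2 difference of 6.08 ± 1.26 (limma, adjusted p = 0.0247, n = 3 against 3). The lectins Cd209d and Cd209a rose by 5.47 ± 0.68 (adjusted p = 6.79e-04) and 5.33 ± 0.81 (adjusted p = 0.00288), and S100a4 by 5.62 ± 1.13 (adjusted p = 0.0198). Timd4, a macrophage receptor for phosphatidylserine encoded near Havcr1, averaged 73.1 TPM in positive cells and was listed at 0 in the negative ones (adjusted p = 0.0308). Pcp4, a calmodulin-binding protein gene, was lower at -4.21 ± 0.61 (adjusted p = 0.00191) and Treml2 at -1.52 ± 0.28 (adjusted p = 0.0114). In all, 111 genes passed, 106 higher and 5 lower, and 10 of 30 lists passed by camera, 1 of them with an estimated correlation. Dendritic cell genes rose by a median of 3.06 (adjusted p = 2.02e-11, and 0.0107 with an estimated correlation), with 3 of 10 called and 8 adjusted over the list alone. Macrophage genes rose by 2.65 (adjusted p = 5.66e-09, but adjusted p = 0.118 with an estimated correlation), with 3 of 11 called and 7 adjusted over the list alone, and by 1.55 without TIM-1 negative replicate 1. Cell cycle genes rose by 1.71 (adjusted p = 5.66e-09, but adjusted p = 0.402 with an estimated correlation), with 1 of 20 called and 4 adjusted over the list alone. NK cell genes rose by 1.25 (adjusted p = 0.0317, but adjusted p = 0.405 with an estimated correlation), with 2 of 7 called and 2 adjusted over the list alone. Neutrophil genes averaged 182 TPM in TIM-1 positive replicate 1 against 2.37 and 2.83 TPM in the other 2, and 91.2 TPM in TIM-1 negative replicate 1. The mean of the B cell identity genes was 645 ± 107 TPM in positive cells and 758 ± 452 TPM in negative cells. The calls of Cd209d, Cd209a and Pcp4 held with any 1 library left out, and those of Ccl8, S100a4, Timd4 and Treml2 did not. The count of called genes was 46 without TIM-1 positive replicate 1 and 63 without TIM-1 negative replicate 1. It was 0 in a fit of the 6 draining node libraries alone.

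In non-draining nodes the called genes with the largest differences included genes of cell division. Ccnb2 rose by 4.69 ± 0.79 (limma, adjusted p = 0.0131, n = 3 against 3), Cdkn3 by 3.83 ± 0.65 (adjusted p = 0.0131), Cdca3 by 3.82 (adjusted p = 0.0382) and Tcf19 by 4.60 ± 0.69 (adjusted p = 0.00561). Pla2g2d, a secreted phospholipase, rose by 3.50 ± 0.62 (adjusted p = 0.018), and Fam214b was lower at -3.34 ± 0.61 (adjusted p = 0.0236). In all, 27 genes passed, 26 higher and 1 lower, and 9 of 30 lists passed by camera, 0 of them with an estimated correlation. The cell cycle list rose by a median of 1.68 (adjusted p = 1.89e-16, but adjusted p = 0.249 with an estimated correlation), with 1 of 20 called and 10 adjusted over the list alone. The macrophage list rose by 1.41 (adjusted p = 7.52e-06, but adjusted p = 0.249 with an estimated correlation). Of its 11 genes 0 were called by limma, 3 had an unadjusted p under 0.05 and 1 passed adjusted over the list alone. The T cell list rose by 0.68 (adjusted p = 0.0193, but adjusted p = 0.734 with an estimated correlation, and 0.0857 with B cell identity scaling). That rise came from TIM-1 positive replicates 2 and 3, with T cell means of 222 and 159 TPM, while replicate 1 at 58.7 TPM lay below all 3 negative libraries. The B cell identity list was lower by -0.53, with all 12 negative (adjusted p = 0.0216, but adjusted p = 0.849 with an estimated correlation). Of the 10 and 12 genes 0 were called by limma, 0 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone. Each of the 6 named calls was lost with at least 1 library left out. The count of called genes was 12, 10 and 15 without TIM-1 negative replicates 1, 2 and 3, and 82 without TIM-1 positive replicate 3. It was 3 with B cell identity scaling, under which the median over all genes moved from -0.11 to 0.33.

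In spleen, few single genes separated TIM-1 positive from TIM-1 negative cells. Ms4a4b, a membrane protein gene of T cells, was lower at -4.88 ± 0.57 (limma, adjusted p = 0.00102, n = 3 against 3), with 0.717 TPM in positive and 45.8 TPM in negative cells. Gchfr, a regulator of tetrahydrobiopterin synthesis, rose by 2.47 ± 0.42 (adjusted p = 0.038). The other called genes were Grk4 (1.49 ± 0.24, adjusted p = 0.0283), Gm20594, A630089N07Rik and Gm17821, all higher, and of the genes called higher all but Grk4 were named after their values were seen. The values of Grk4 and Gm20594 are uncertain as said above, as is that of A630089N07Rik, whose transcript shares a stretch with 204 other genes. The call of Gm20594 was lost with quantile normalization (0.56, adjusted p = 0.966), with B cell identity scaling (2.614, adjusted p = 0.389) and in the fit of the spleen libraries alone (2.145, adjusted p = 0.0783). For so abundant a gene the loss with quantile normalization decides little, as said above. In all, 6 genes passed, 5 higher and 1 lower, and 5 of 30 lists passed by camera, 0 of them with an estimated correlation. Macrophage genes rose by a median of 1.73 (adjusted p = 7.75e-12, but adjusted p = 0.0859 with an estimated correlation). By limma 0 of 11 were called, 6 had an unadjusted p under 0.05 and 4 passed adjusted over the list alone. Plasma cell genes rose by 0.51 (adjusted p = 5.51e-07, but adjusted p = 0.13 with an estimated correlation), and T cell genes were lower by -1.72 (adjusted p = 3.89e-06, but adjusted p = 0.379 with an estimated correlation). By limma 0 genes of either list were called, 3 of 15 and 5 of 10 had an unadjusted p under 0.05, and 0 and 4 passed adjusted over the list alone. Without TIM-1 positive replicate 3, which stood apart and had the lowest T cell mean at 9.38 TPM, the T cell list was at -1.52 and the macrophage list at 2.1. The calls of Ms4a4b and Gm20594 held with any 1 library left out, and those of the other 4 genes did not. The count was 5 with the replicate block, 2 with the block within tissue, 2 without TIM-1 negative replicate 1 and 2 without TIM-1 negative replicate 2, and 0 in a fit of the 6 spleen libraries alone. It was also 0 with B cell identity scaling, which moved the median over all genes from -0.23 to 0.15.

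A further test asked whether the TIM-1 difference itself depended on the tumor-draining site. Dendritic cell genes differed more between TIM-1 positive and negative cells in draining than in non-draining nodes, by a median of 2.19 on the log2 scale (camera, adjusted p = 8.77e-08, and 0.0476 with an estimated correlation), with 1 of 10 called and 4 adjusted over the list alone. That gene was Clec10a, a lectin of dendritic cells and macrophages, whose TIM-1 difference was larger in draining nodes by 6.18 ± 0.85 (limma, adjusted p = 0.0118). Chchd6, a mitochondrial cristae gene, differed by 5.21 ± 0.92 (adjusted p = 0.0337) and Klra17, a lectin-like receptor gene, by 4.74 ± 0.70 (adjusted p = 0.0156). Havcr2 was at 9.52 ± 4.76 TPM in TIM-1 positive cells of draining nodes, and its TIM-1 difference there was larger by 3.26 (adjusted p = 0.0206), a gene singled out here after its value was seen. The dendritic cell list differed in the same direction, so whether B cells or dendritic cells in the sort carried Havcr2 cannot be told apart. In all, 15 genes passed, all of them higher. Havcr1 itself did not pass (2.15, adjusted p = 0.861). The call of Clec10a held with any 1 of these libraries left out. Those of Chchd6, Klra17 and Havcr2 did not, and each was lost without any 1 of the 3 TIM-1 negative libraries of non-draining nodes. The count was 2, 2, 6 and 8 without TIM-1 positive replicates 1 and 2 and TIM-1 negative replicates 1 and 2 of draining nodes. It was 8 without TIM-1 positive replicate 1 of non-draining nodes and 2, 2 and 1 without TIM-1 negative replicates 1, 2 and 3 there. It was 4 without both libraries that stood apart, and 0 with a filter of 5 TPM, with the block within tissue or in a fit of these 12 libraries alone. B cell identity scaling moved the median over all genes from 0.20 to -0.35.

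The TIM-1 difference in spleen was set against the mean of that in both kinds of node. Ms4a4b alone passed, with a difference of -5.09 ± 0.70 (limma, adjusted p = 0.0172), a call lost with the block within tissue. T cell genes as a list differed by a median of -1.94 (camera, adjusted p = 3.57e-06, but adjusted p = 0.399 with an estimated correlation). By limma 0 of these 10 genes were called, 5 had an unadjusted p under 0.05 and 5 passed adjusted over the list alone. The count of 1 was 0 without replicates 1 or 2 of TIM-1 negative spleen, replicate 1 of TIM-1 positive spleen, replicate 2 of TIM-1 positive draining nodes, replicate 2 of TIM-1 positive non-draining nodes or replicates 1 or 2 of TIM-1 negative non-draining nodes. It was 5 without replicate 3 of TIM-1 positive spleen and 2 without replicate 3 of TIM-1 negative draining nodes.

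The next comparison asked what sets B cells inside the tumor apart from B cells of the lymphoid tissues. Tumor libraries held large amounts of melanocyte and melanoma transcripts. Dct, an enzyme of melanin synthesis on chromosome 14 from 118012790 to 118052244 in GRCm38, averaged 2602 TPM in the tumor and 0.0122 TPM in the lymphoid tissues, a log2 difference of 11.23 ± 0.28 (limma, adjusted p = 5.44e-12, n = 3 against 9). The pigment genes Tyrp1, Pmel, Mlana and Slc45a2 rose by 11.12 ± 0.32, 9.93 ± 0.34, 9.61 ± 0.45 and 8.67. Gpnmb, a membrane glycoprotein of melanosomes, rose by 10.52 ± 0.24 and Ptgds, a prostaglandin synthase, by 10.54 ± 0.23. The hemoglobin genes Beta-s and Hba-a1 rose by 8.17 ± 1.35 and 8.12 ± 1.17, and the metal-binding gene Mt1 by 8.17 ± 0.65. The hemoglobin rise was against the nodes, since against spleen alone Beta-s differed by 2.08 ± 1.65 (adjusted p = 0.411) and Hba-a1 by 1.63 ± 1.43 (adjusted p = 0.463), and neither passed. The named genes that fell belonged mostly to T and NK cells. Cd3g, Cd3d and Cd3e, chains of the T cell receptor complex, had log2 differences of -5.97 ± 0.41, -5.36 and -5.07 ± 0.31, Lat of -5.64 ± 0.27, Ms4a4b of -5.54, Nkg7 of -5.24 and Cd8b1 of -4.99. In all, 4073 of 12213 genes passed, 2583 higher and 1490 lower, and 2545 of them by at least 2-fold. Against single tissues the counts were 3158 for draining nodes, 3365 for non-draining nodes and 2918 for spleen. The split was 2030 to 2511 with quantile normalization and 7614 to 285 with B cell identity scaling, under which the median over all genes moved from 0.04 to -0.18 and to 0.93. The count was 2360 without tumor replicate 1 and 2321 without tumor replicate 2. Without tumor replicate 3 it was 4762, with 2494 higher and 2268 lower.

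Of the 28 lists tested in the tumor, 7 rose and 9 fell by camera, and with an estimated correlation 0 passed. All 10 melanoma genes rose, by a median of 9.14 (adjusted p = 8.45e-16, but adjusted p = 0.0775 with an estimated correlation), and all 10 passed adjusted over the list alone. All 20 cell cycle genes rose, by a median of 3.22 (adjusted p = 2.93e-10, but adjusted p = 0.196 with an estimated correlation), including Rrm2 (4.78), Cdk1 (4.33 ± 0.42) and Top2a (4.11). Of 19 hypoxia and glycolysis genes, 17 rose, by a median of 2.58 (adjusted p = 2.04e-12, but adjusted p = 0.18 with an estimated correlation). Tpi1 (4.27), Pgk1 (3.76 ± 0.26) and Gapdh (2.96) encode enzymes of glycolysis, and Bnip3 (4.82 ± 0.29, adjusted p = 6.64e-08) is a mitophagy gene. The melanoma genes averaged 1370, 1288 and 528 TPM in tumor replicates 1, 2 and 3, the glycolysis genes 2149, 1972 and 742 TPM, and the cell cycle genes 139, 113 and 44.6 TPM. Immediate-early genes rose by a median of 2.50, with 12 of 16 called (adjusted p = 5.47e-06, but adjusted p = 0.249 with an estimated correlation), including the activation genes Fos (5.32 ± 0.42), Ier3 (5.98), Fosb (3.63) and Junb (2.88). They averaged 189, 274 and 582 TPM in the 3 tumor libraries, against 74.8 TPM in the lymphoid ones. All 11 genes of the heat shock and dissociation stress list, a list of sample handling, rose, by a median of 1.62 (adjusted p = 1.96e-07, but adjusted p = 0.0775 with an estimated correlation), including Hspa1a (7.0 ± 0.62) and Hsp90aa1 (2.72 ± 0.19). They averaged 850, 583 and 627 TPM in the 3 tumor libraries, against 271 TPM in the lymphoid ones. Of 14 unfolded protein response genes, 11 rose, by a median of 0.94 (adjusted p = 6.16e-05, but adjusted p = 0.192 with an estimated correlation), including Dnajb9 (1.85) and Hspa5 (1.24). Erythroid genes rose by a median of 6.22 with 4 of 5 called (adjusted p = 0.0175, but adjusted p = 0.355 with an estimated correlation, and 0.221 with B cell identity scaling). Against spleen alone the erythroid list was at 1.63 (adjusted p = 0.564) and limma called 0 of 5, with 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone, so this rise too was against the nodes.

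Genes of B cell identity and antigen presentation were lower in the tumor libraries. Of 12 B cell identity genes, 9 fell over all genes tested and 11 adjusted over the list alone, with a median of -0.92 (camera, adjusted p = 3.65e-06, but adjusted p = 0.257 with an estimated correlation). Ms4a1, which encodes CD20, was lower at -1.57 ± 0.23 (adjusted p = 1.46e-04) and the antigen receptor chains Cd79b and Cd79a at -1.13 and -1.08 ± 0.19. The list averaged 361, 459 and 892 TPM in tumor replicates 1, 2 and 3, against 1110 TPM in the lymphoid libraries. All 10 MHC class II genes fell, by a median of -1.07 (adjusted p = 3.65e-06, but adjusted p = 0.257 with an estimated correlation), including H2-Ab1 (-1.24 ± 0.23) and H2-Oa (-1.41). Of 11 MHC class I genes, 9 fell, and 10 adjusted over the list alone, with a median of -0.87 (adjusted p = 3.65e-06, but adjusted p = 0.249 with an estimated correlation), including the proteasome subunit Psmb8 (-1.21 ± 0.16). Of 20 type I interferon genes, 11 fell and 1 rose over all genes and 12 passed adjusted over the list alone, with a median of -0.84 (adjusted p = 9.37e-04, but adjusted p = 0.257 with an estimated correlation), including Usp18 (-2.55 ± 0.46) and Mx1 (-2.12). With scaling to the B cell identity genes the medians of the MHC class I and interferon lists turned to 0.11 and 0.10, and that of MHC class II was -0.09. The calls of H2-Ab1, Psmb8, Mx1, Cd22 and Cd72 were lost with it. This scaling holds the B cell identity genes near 0 by construction, so it is no test of them. TPM is a share of all transcripts, and the melanoma genes averaged 1370, 1288 and 528 TPM in these 3 tumor libraries. Of the 1490 genes called lower, 1100 had their highest and 158 their lowest tumor value in replicate 3, an order that rests on 1 library. For the B cell identity and MHC genes, a smaller share of B cell RNA cannot be told apart from a change in the B cells. Co-stimulatory genes fell by a median of -1.43, with 10 of 14 lower and 1 higher (adjusted p = 1.58e-05, but adjusted p = 0.0775 with an estimated correlation). Cd27 (-4.05 ± 0.31) and Cd28 (-2.85) were lower, and the ligand Tnfsf9, named after its value was seen, was higher (3.06). Co-inhibitory genes fell by a median of -0.81, with 7 of 19 called and 9 adjusted over the list alone (adjusted p = 7.1e-04, but adjusted p = 0.257 with an estimated correlation), including Cd200 (-1.61), Cd22 (-1.31) and Cd72 (-1.09). The checkpoint gene Lag3, chosen after its value was seen, was also lower (-1.50), a call lost without tumor replicate 1 (adjusted p = 0.0898) or 2 (0.077), with a pseudocount of 5 (0.0582), with array weights (0.124) and with all 30 libraries in the fit (0.0581). Of 7 B cell cytokine genes, 4 fell, and 5 adjusted over the list alone, with a median of -1.68 (adjusted p = 7.1e-04, but adjusted p = 0.249 with an estimated correlation), including the lymphotoxin gene Lta (-2.80 ± 0.22, adjusted p = 5.77e-07) and Tnf (-2.63). All 10 T cell genes fell, by a median of -4.61 (adjusted p = 2.04e-12, but adjusted p = 0.0775 with an estimated correlation), as did 4 of 5 NK cell genes, by -2.55 (adjusted p = 8.19e-04, but adjusted p = 0.18 with an estimated correlation). The T cell genes averaged 15.6 ± 8.59 TPM in the tumor, 97.5 ± 22.3 TPM in draining nodes, 113 ± 20.4 TPM in non-draining nodes and 37.8 ± 11.5 TPM in spleen, although the gate removed CD3e positive cells. For falls such as those of Cd27, Cd28, Lag3 and Lta, less T cell RNA in the tumor libraries cannot be told apart from a change in the B cells.

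**Figure D4:**
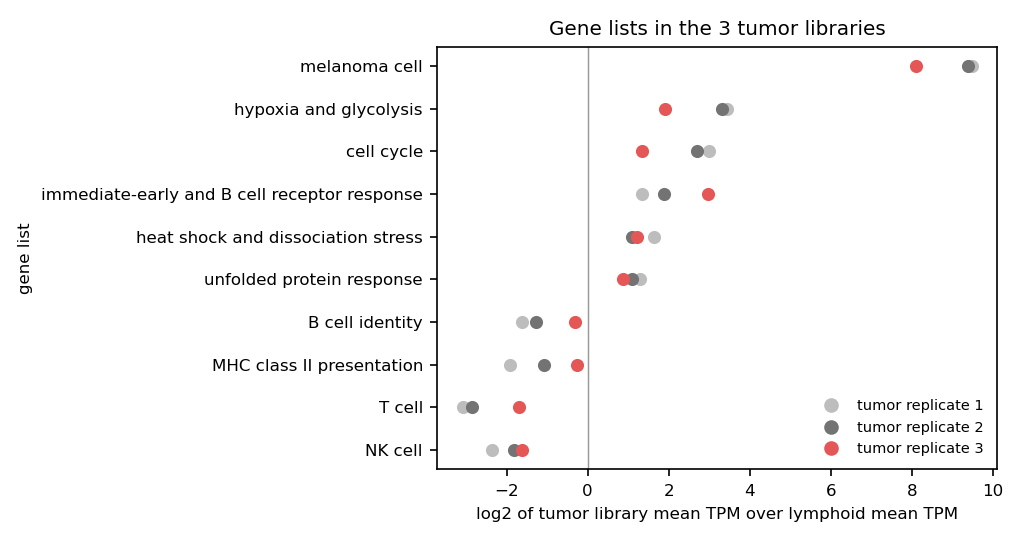
Log2 ratio of each tumor library's mean TPM to the mean of the lymphoid all B cell libraries for 10 gene lists (3 points per list, replicate 3 in red). The melanoma genes averaged 1370, 1288 and 528 TPM in tumor replicates 1, 2 and 3.

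Spleen and lymph nodes differ in the B cell subsets they hold, and all B cells of both were compared. Marginal zone genes, the program of a B cell subset of the spleen, rose in spleen by a median of 1.27 over 9 genes (camera, adjusted p = 8.35e-09, and 0.0394 with an estimated correlation). Of these, 2 were called over all genes and 6 adjusted over the list alone, including the sphingosine phosphate receptor S1pr3 (2.60 ± 0.48, limma adjusted p = 0.0161) and Dtx1, a Notch target (1.45, adjusted p = 0.025). The fatty acid transporter Cd36 rose by 2.67 ± 0.40, and Fcna, a lectin of splenic macrophages, by 4.25 ± 0.47 (adjusted p = 6.36e-04). T cell genes fell, with 9 of 10 called and a median of -2.85 (adjusted p = 2.35e-25, and 0.0376 with an estimated correlation), including Cd3e (-3.08 ± 0.32, adjusted p = 5.54e-04) and Cd8b1 (-3.76 ± 0.47). Hba-a1 rose by 9.73 ± 1.24 (adjusted p = 0.00148), at 53.7, 2288 and 24254 TPM in the 3 spleen libraries. The erythroid list rose by 3.20, with 2 of 5 called and 4 adjusted over the list alone (adjusted p = 3.75e-09, but adjusted p = 0.116 with an estimated correlation). Plasma cell genes rose by a median of 0.48, with 1 of 14 called and 5 adjusted over the list alone (adjusted p = 2.28e-08, but adjusted p = 0.116 with an estimated correlation). The called gene was Sdc1 (1.54, adjusted p = 0.0313). Its product CD138 is named in the sort gate of both spleen and nodes, so what it says about plasma cells stays open. Igj, named after its value was seen, differed by 6.95 and did not pass (adjusted p = 0.0832), but passed with array weights (0.0022) and with only the libraries of this comparison (0.00102). Macrophage genes rose by a median of 1.24, with 2 of 10 called (adjusted p = 7.92e-06, but adjusted p = 0.292 with an estimated correlation), and 3 higher and 1 lower adjusted over the list alone. The cell cycle and B cell identity lists rose by medians of 0.65 over 20 genes and 0.32 over 12 genes, with 0 genes called in either by limma, 5 and 2 with an unadjusted p under 0.05, and 1 and 0 adjusted over the list alone. Their adjusted p of 2.85e-08 and 3.58e-05 became adjusted p = 0.292 and 0.472 with an estimated correlation. Co-stimulatory genes were lower by a median of -0.55 with 3 of 14 called and 4 adjusted over the list alone (adjusted p = 0.00131, but adjusted p = 0.14 with an estimated correlation). Immediate-early genes were lower by -0.81 with 1 of 16 called, Fos at -2.81 ± 0.44, and 2 adjusted over the list alone (adjusted p = 7.2e-05, but adjusted p = 0.373 with an estimated correlation). The type I interferon and NK cell lists were lower by -0.42 and -1.40 (adjusted p = 0.00866 and 0.00943, but adjusted p = 0.472 and 0.292 with an estimated correlation). Both calls were lost with B cell identity scaling (adjusted p = 0.0726 and 0.0844), where the medians were -0.65 and -1.58. Of 20 interferon genes 0 were called by limma, with 5 at an unadjusted p under 0.05, and adjusted over the list alone 1 was higher and 1 lower. Of 5 NK cell genes 1 was called, with 3 adjusted over the list alone. The calls of S1pr3, Dtx1 and Sdc1 were each lost without spleen replicate 2, among other libraries, and those of Fcna, Cd36, Cd3e, Cd8b1, Hba-a1 and Fos held with any 1 library left out. In all, 130 genes passed, 44 higher and 86 lower, and with B cell identity scaling the split was 17 to 118 with a median over all genes of -0.31 in place of -0.04. The count was 84, 75 and 75 without spleen replicates 1, 2 and 3.

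B cells of draining and non-draining nodes were compared to see whether the tumor changed the node that drains it. Type I interferon genes were lower in draining nodes by a median of -0.39 over 20 genes, 16 of them negative (camera, adjusted p = 0.00193, but adjusted p = 0.893 with an estimated correlation). Their most abundant members, Bst2 and Stat1, differed by -0.13 and -0.02. By limma 0 of the 12213 genes passed, and 420 had an unadjusted p under 0.05. Of the 20 interferon genes 0 were called, 4 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone. In simulated data for this comparison, limma recovered 29% of genes with a log2 change of 1 and 67% of those with a change of 2.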

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

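The counts over other splits of the libraries were planned, while the tests of the 3 patterns at the end, the fits without the libraries that stood apart and the scaling to B cell identity genes were chosen only after the results were seen.

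The TIM-1 difference was itself different between draining and non-draining nodes for 15 genes by the test of that difference. Of 100 splits of the libraries, 1, the real one, gave as many, and the highest of the others gave 12. That split exchanged the TIM-1 positive libraries of both kinds of node whole and mixed only the negative ones. It therefore held the difference between the TIM-1 positive cells of the nodes. The real count was the highest of the 100, but it does not set a changed TIM-1 difference apart from that one. Clec10a differed by 6.18, Chchd6 by 5.21 and Klra17 by 4.74 on the log2 scale. By the same contrast the dendritic cell list differed by a median of 2.19 (adjusted p = 8.77e-08, and 0.0476 with an estimated correlation). The co-inhibitory list differed by 0.78 (adjusted p = 0.0431), the MHC class II list by 0.76 (adjusted p = 0.0144) and the T cell list by -0.81 (adjusted p = 0.0144), and these 3 had adjusted p = 0.793 with an estimated correlation. Without replicate 1 of TIM-1 negative draining nodes they were at 0.38 (adjusted p = 0.1), 0.075 (0.533) and -0.048 (0.777).

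Between spleen and nodes the TIM-1 difference itself differed for 1 gene, Ms4a4b, at -5.09. Of 100 splits, 16 gave at least as many and the highest of the others gave 30, so chance cannot be excluded, and a split with that many calls points to a structure of the samples: it moved the 3 TIM-1 positive spleen libraries together into another group, so it held the difference between spleen and nodes. Lists that differed by this test were germinal center genes at -2.07 (adjusted p = 3.18e-04), cell cycle genes at -1.23 (0.00343), T cell genes at -1.94 (3.57e-06), NK cell genes at -1.51 (0.00113), co-stimulatory genes at -1.22 (0.0161), dendritic cell genes at -1.14 (0.0193), plasma cell genes at 0.32 (0.00427) and unfolded protein response genes at 0.15 (0.0361). With an estimated correlation their adjusted p lay between 0.311 and 0.627. Without both libraries that stood apart, co-stimulatory genes were at -0.88 (adjusted p = 0.11), dendritic cell genes at -0.79 (0.205) and unfolded protein response genes at -0.032 (0.976).

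For the TIM-1 mean of 3 tissues, 1 of 100 splits, the real one, gave 180 genes and the highest of the others 3. For the tumor, 1 of 100 gave 4073 and the highest of the others 147. Chance can be excluded for both. For spleen against nodes, 2 of 100 splits gave 130 or more, the real one and one with 132, which exchanged 1 draining with 1 non-draining library and kept the spleen libraries together, and at 2 of 100 chance can be excluded. Within a tissue the 10 splits are too few for a share under 0.05: the real counts were 111, 27 and 6 in draining nodes, non-draining nodes and spleen and 0 for draining against non-draining nodes, and the highest of the others 1, 1, 6 and 1. In spleen 2 splits gave 6 genes. The other of these parted fewer pairs of the same number. Only 4 splits, the real one included, part all 3 pairs, and the highest of the others among them was 3. So few splits cannot decide, that restriction was not part of the planned counts, and the labels give no source for the pairing.

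Transcripts that separated TIM-1 positive from negative libraries completely in every tissue, Gm20594 and Grk4 among them, were weighed against a repeated sequence and against the number of genes detected. A stretch of at least 300 bases at 80% identity or more that 20 other genes also hold was found in 38.6% of those with a reference transcript (17 of 44), against 2.6% of expression-matched genes (9 of 344, Fisher's exact test, two-sided, p = 5.57e-12). The search counted any shared stretch and did not tell a repeat from a stretch shared by related genes, and Gapdh, with 235 other genes, was among the 17. The matched genes were matched for expression and not for transcript length. Reads of a shared stretch may account for some of these transcripts, but as the cause of all of them a repeat misses the bound of more than 50% that was set for it. Fewer genes reached 1 TPM in TIM-1 positive libraries in 2 of the 3 tissues (-158 with SE 29.1 in non-draining nodes and -424 with SE 172 in spleen), while draining nodes went the other way (1213 with SE 848), so this leaves library complexity open. The set also held phagocyte genes, such as Lyz2 and C1qa, and cell cycle genes, such as Nek2 and Kif23. Their transcripts share a stretch with 1, 0, 0 and 0 other genes in that order, so no single cause need cover the whole set. Macrophages in the sort, weighed next, were not tested as a source of these transcripts. A state of TIM-1 positive cells that changes these RNAs stays open and was not tested.

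Macrophage and dendritic cell transcripts were higher in TIM-1 positive libraries, and the gate named no myeloid marker. As written for all B cells it does ask for CD138, and whether such cells would pass that was not tested. A second macrophage list of 21 genes, 19 of them measured, had a median difference of 0.73 with 18 of 19 positive (p = 8.05e-09, and p = 0.00429 with an estimated correlation), at 1.47 in draining nodes and 0.72 in spleen but only 0.25 in non-draining nodes, with 12 of 19 positive (p = 0.0157, but p = 0.167 with an estimated correlation). Macrophages in the TIM-1 positive sort could therefore be a source, least clearly in non-draining nodes, although 6 of the 21 genes reached 10 TPM in all B cells of lymphoid tissue and only 1 of the 19 was called. A lower B cell share that raises all other cell types alike is argued against in spleen. There the macrophage list was at 1.73 and the T cell list at -1.72, 3.45 apart (bootstrap SE 0.56) and at least 3.12 apart with any 1 library left out. In non-draining nodes both lists rose, at 1.41 and 0.68, only 0.73 apart (SE 0.39, and -0.22 without TIM-1 positive replicate 1). That share cannot be told apart there from macrophages in the sort. The SEs of these gaps resampled the genes of the lists, so they carry no spread between libraries. In draining nodes the 2 lists lay 2.82 apart (SE 0.82) but, without TIM-1 negative replicate 1, both rose, at 1.55 and 0.69 (0.86 apart, SE 0.64), so that gap rests on 1 library and the share stays open, as do myeloid genes made by the B cells themselves, which were not tested.

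Tumor libraries held melanoma transcripts although the gate on CD45 would remove melanoma cells, and tumor replicate 3 had the lowest melanoma level. Of the 37 called cell cycle and glycolysis genes, 100% had their lowest tumor value in replicate 3, against 73.8% of all 2583 genes higher in the tumor. Of the called immediate-early genes 16.7% were lowest there (2 of 12) and of the heat shock genes 45.5% (5 of 11), but an order that rests on 1 library cannot decide, and for all 4 groups melanoma RNA and a response of the B cells cannot be told apart. Only 1 of the 11 melanoma genes reached 10 TPM in all B cells of lymphoid tissue. A response of tumor B cells to their tissue and, for the immediate-early and heat shock genes, stress from dissociation of the tissue stay open and were not tested.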

How the results depend on the processing

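The fits without the 2 libraries that stood apart and the scaling to B cell identity genes were chosen after seeing the data. So were the TPM recomputed without Rn45s, Gm20594 and the hemoglobin genes and, for lists, median-of-ratios scaling. The cause of the changes below was not tested unless stated. Of the values of named genes under alternatives, 691 lost a call, 36 gained one, 4 were of called genes that turned and 8656 counted as unchanged. Of those of lists, 137 lost a call, 41 gained one, 1 was of a called list whose camera direction turned and 2029 counted as unchanged. A result not called in the main fit counted as unchanged even if it turned. So did a called list whose median alone changed sign, such as MHC class I in the tumor with B cell identity scaling (0.112). The 4 genes, Nfkb2 at 0.229, Psmb10 at 0.093, Tapbp at 0.112 and Tyrobp at 0.049, turned in the tumor comparison with B cell identity scaling, and the unfolded protein response list turned to -0.032 in the spleen difference of TIM-1 without both libraries. Unknown depth limits what a value of 0 or near 0 can show.

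For the TIM-1 mean, 180 genes became 409 with array weights, 447 with all 30 libraries in the fit, 322 without both libraries that stood apart (156 of them shared), 116 with B cell identity scaling and 95 with the block within tissue. In draining nodes 111 became 73 with a pseudocount of 0.1, 177 with array weights, 265 with all 30 libraries, 71 with the block within tissue and 0 with only its own 6 libraries. In non-draining nodes 27 became 42 with no trend, 94 with all 30 libraries, 15 with only its own libraries, 13 with the block within tissue, 124 without both libraries (27 shared) and 3 with B cell identity scaling. In spleen 6 became 12 with a pseudocount of 0.1, 27 with array weights, 16 with all 30 libraries, 0 with only its own libraries, 2 with the block within tissue and 0 with B cell identity scaling.

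For the TIM-1 difference between nodes, 15 became 28 with no filter, 0 with a filter of 5 TPM, 3 with quantile normalization, 24 with no trend, 50 with all 30 libraries, 0 with only its own libraries, 0 with the block within tissue, 4 without both libraries (3 shared) and 23 with B cell identity scaling. For that between spleen and nodes, 1 became 2 with a pseudocount of 0.1, array weights or no trend, 0 with a pseudocount of 5, 4 with no filter, 4 with all 30 libraries, 0 with the block within tissue, 6 without both libraries and 0 with B cell identity scaling. In the tumor 4073 became 2545 with a 2-fold minimum, which can only remove genes, and 7899 with B cell identity scaling. For draining against non-draining nodes 0 became 1 with no filter, array weights, no trend or all 30 libraries. For spleen against nodes 130 became 257 with array weights and 37 with all 30 libraries. Lists called over the TIM-1 mean, tumor, spleen and node comparisons together fell from 36 to 5 with an estimated correlation.

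With each library left out in turn the counts ran from 97 to 327 for the TIM-1 mean, 46 to 104 in draining nodes, 10 to 82 in non-draining nodes, 2 to 7 in spleen, 1 to 15 for the difference between nodes, 0 to 5 for that between spleen and nodes, 2321 to 4762 in the tumor, 0 to 0 for draining against non-draining nodes and 75 to 146 for spleen against nodes. With the replicate number as a block over all tissues they were 171, 111, 24, 5, 11, 1, 4099, 0 and 114 in that order, and lists called numbered 35. Whether a number marks a mouse is left open by the labels. In 14 of the 45 pairs of groups all 6 libraries went best with their own number, a hint from the data. The fit of only its own groups gave no separate value for the TIM-1 mean, the spleen difference and the tumor, where these are the same libraries.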

Other observations

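The second correlation between tissues and the test of ribosomal protein genes were chosen only after the results were seen.

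In the tumor, further genes from the lists of survival, homing and plasma cells differed although these lists did not pass. Called were 5 of 8 survival, 9 of 14 homing and 5 of 14 plasma cell genes, against 4073 of all 12213 genes. The tumor libraries also held melanoma RNA and less T cell RNA. Which cells the differences below come from was not tested. The receptor for the survival factor BAFF, Tnfrsf13c, was lower in tumor than in lymphoid libraries at -2.05 ± 0.15 (limma, adjusted p = 3.16e-07, n = 3 against 9), and its relative Tnfrsf13b at -1.67 ± 0.26 (adjusted p = 2.28e-04). Pmaip1, a cell death gene, was higher (1.83, a call lost without tumor replicate 3), and Bcl2, which protects from it, lower (-1.20). Among homing genes, the adhesion receptor Cd44 rose by 2.54 ± 0.22 (adjusted p = 1.65e-06), and the chemokine receptor Ccr7 by 1.70 ± 0.26 (adjusted p = 2.12e-04). Cxcr6, another chemokine receptor, was lower at -2.77. Of plasma cell genes, the chaperone Fkbp11 rose by 2.40, while Mzb1 was lower at -1.13. Sdc1 rose by 2.12 ± 0.30 (adjusted p = 1.2e-04), but its product CD138 is named in the sort gate of all these libraries, so what this says about plasma cells stays open. The interferon-induced chemokine Cxcl10 rose by 4.56 ± 0.45 and the transcription factor Irf8 was lower at -1.14. The calls of Bcl2, Mzb1 and Irf8 were lost with B cell identity scaling.

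Whether the TIM-1 differences of draining nodes and spleen go together across genes was tested. Over the genes called in the mean of 3 tissues, Pearson's r was 0.693, but the same libraries chose these genes, so that value decides nothing (highest of the other splits 0.633). Over the 200 genes with the smallest p in non-draining nodes, whose libraries enter neither difference, r was 0.465, and 74% of the genes had the same sign. Of 100 splits, 2 gave an r as high, with 0.487 the highest of the others and -0.01 their median. Over all 12539 genes r was 0.247 between draining and non-draining nodes, 0.216 between draining nodes and spleen and 0.233 between non-draining nodes and spleen. These correlations are across genes, which are not independent replicates.

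Genes of cytoplasmic ribosomal proteins were tested as a hypothesis of a shared fall with TIM-1. Their median log2 difference over 82 genes was -0.16 (p = 5.12e-14, but p = 0.126 with an estimated correlation), with 9 called lower, and -0.17, -0.12 and -0.15 in draining nodes, non-draining nodes and spleen. Without TIM-1 negative replicate 1 of draining nodes the value there was -0.09 (p = 0.00107, but p = 0.485 with an estimated correlation). Over the 3 tissues it was -0.02 with quantile normalization, -0.04 with median of ratios and 0.11 with B cell identity scaling, so its direction rests on the scaling and the hypothesis stays undecided.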
